A study of Bradyrhizobium japonicum with 12 samples.

How the data were processed

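Bradyrhizobium japonicum USDA 110, a soil bacterium that nodulates soybean, was starved of sulfur for 4 days and then grown at 30 °C in 15 ml cultures with 2 mM sulfate, HEPES, taurine or cysteine, per the labels' protocols. Cultures started at an OD600 of 0.2 and were stopped at an OD600 between 0.5 and 0.6, per the labels' protocols. RNA of 2 sources was hybridised to each array of a 2-colour microarray. Each of the 6 possible pairs of the 4 sources had 2 arrays, 12 arrays in all. The series' design text states 3 biological materials and a dye swap. It does not tie materials to arrays, so p-values here measure only the spread between these arrays, which may be technical for arrays of the same pair.

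The deposited values are log10 ratios of the intensities of the 2 channels, as read from the values themselves; the authors' image processing, background correction and normalization are not given in the sources used here. All of the 60 most frequent non-zero values were log10 of a ratio of whole numbers with a denominator up to 200, the ratio matching within 1e-08, and 0 of them were such ratios in base 2 or base e. The simplest fraction within rounding was taken as each spot's pair of intensities, in lowest terms, so that recovered intensities are lower bounds. Of the 101748 values, 80.5% gave a geometric mean intensity below 3000, against 0.78% of random values; of simulated whole-number ratios, 99.98% were recovered. The median recovered intensity per array ran from 533 to 1856. Array medians ran from -0.242 to 0.0552 on the log10 scale, so the table was not centred. There were 0 missing values, and 0 value columns lay outside the 12 samples.

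The plan made before the data were examined used the values without further normalization. Because the table proved not to be normalized, values were instead multiplied to the log2 scale and each array was corrected by loess (limma's loessFit, span 0.4, 4 iterations) against the 75th percentile, over arrays, of a probe's median-centred recovered intensity. That change was made after trial fits had been seen; the values as deposited and median-centred were kept as alternatives and called the same number of genes, 0. The array platform's annotation named 1 gene for 8462 of 8479 probes, several for 0 and none for 17. Probes of a gene were averaged, giving 8268 genes. Of 191 genes with several probes, 33 had probes that differed by over 1 log2 in some comparison.

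The scale is settled by the values, the centring is none, and the direction is likely but not settled. On both arrays of a pair the labels put Cy5 on the source named first, with the channel order exchanged, whereas the design text states a dye swap. As deposited, the 2 arrays of a pair correlated across probes at -0.21 for sulfate and HEPES, -0.29 for sulfate and taurine, -0.84 for sulfate and cysteine, -0.16 for HEPES and taurine, -0.31 for HEPES and cysteine, and 0.37 for taurine and cysteine. The rule fixed before the data were examined turned array 2 where the arrays of the pairs correlated negatively and left it where positively. The sign of every array 2 was turned, following the other 5 pairs. Taken for its own pair alone, the rule would have left taurine and cysteine array 2 unturned. After loess and turning, that pair correlated at -0.17 and the other 5 between 0.27 and 0.87. The sign of the whole table was taken from array 1 as the source named first over the source named second. Genes of sulfonate use then came out higher with sulfonates; the direction was not chosen from them, but they had been seen.

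The array numbers paired the arrays: over 15 comparisons of pairs, the deviations of equally numbered arrays from their pair mean correlated across genes between 0.37 and 0.81. The number also marks the orientation of the dyes, so the fit with the number as a replicate block removes a dye effect of each gene. Such an effect cancels in a pair mean.

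The 2 turned arrays of a pair were averaged, and the 6 pair means were fitted per gene in limma 3.58.1 (R 4.3.3; lmFit, contrasts.fit and eBayes) as differences of 4 sources, with 3 residual degrees of freedom and 2.68 prior degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The 6 differences between sources, the sulfonates against sulfate and cysteine, and a moderated F test of any difference were tested. The same model on all 12 arrays, with the pair as a random block (consensus correlation 0.0769), as independent arrays, or with the replicate block, was an alternative chosen before the data were examined. Also chosen before the data were examined were centring, scaling, direct arrays only, robust eBayes, each probe on its own, and leaving out each array in turn. A filter on probes with values on all arrays would have removed none and was not run.

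Arrays were simulated with 200 of 8268 genes changed in a source and with spreads taken from these data. The fit of 6 pair means recovered 0% of changes of 1 log2 against sulfate, 28% of 2, 70% of 3 and 90% of 4. Of its calls in the comparisons with sulfate, 5.05% were false. The random block recovered 24%, 74%, 86% and 96%, but 45.5% of its calls were false. With the replicate block, 51.5% were. Any dye effect shared by the pairs was simulated as random spread between the arrays of a pair. The replicate block removes such an effect, so its share may not hold for the real arrays, and the other shares are approximate. All shares also depend on the number of genes changed, and a gene was given the same spread in every pair. Calls from the 12 arrays are therefore given as a way to choose genes to describe, not as established changes. The number of arrays limits the precision.

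The rule for named genes, fixed before the data were examined, took for each pair of sources the genes past the threshold whose 2 direct arrays had the sign of the fitted difference, up to 12 in each direction (3 for HEPES or taurine against cysteine), and members of the sulfonate and sulfate lists. No gene passed in the fit of pair means, so the rule was applied to the random-block fit, a choice made after the values were seen. For 22 gene lists the topics were fixed before the data were examined. Of these, 17 had at least 3 members and were tested with camera (preset correlation 0.01), adjusted over 119 tests. The other 5 had fewer members and were not tested. The annotation held gene symbols without products, so symbols for several lists were written out after values had been seen. That gave all members of the redox and thiol stress (15), ribosomal protein (53) and TCA cycle (14) lists. It also gave 20 of 46 members of chaperones and proteases, 8 of 11 of efflux and metal resistance, and some members of other lists. A further 5 lists were chosen after the data were examined and adjusted apart. Recovery of intensities used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.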

Results

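Transcript levels of 8268 genes were compared among Bradyrhizobium japonicum USDA 110 cells given 1 of 4 sulfur sources: sulfate, the amino acid cysteine, or the sulfonates taurine and HEPES, in which sulfur is bound to carbon. The study addressed how the bacterium assimilates sulfate and sulfonates. Each of the 6 pairs of sources had 2 arrays. Values are fitted log2 differences ± SE over 6 pair means, and their direction is likely, resting on the labels' dyes on array 1. The median SE was 0.24 for a difference of 2 sources. In the limma fit of the 6 pair means, 0 genes passed an adjusted p of 0.05 in any comparison, and genes are described below by their values. Those outside the sulfonate and sulfate lists were picked from the fit of all 12 arrays, in which 45.5% of calls in comparisons with sulfate were false when simulated.

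With taurine, genes of the sulfonate clusters were higher than with sulfate. In bll6449 to bll6455, bll6449 was 3.51 ± 0.62 higher and bll6451 was 2.67 ± 0.51 higher. In bll7007 to bll7011, ssuD (bll7010), the gene of an alkanesulfonate monooxygenase that releases sulfite from sulfonates, was 3.16 ± 0.97 higher, bll7011 was 3.29 ± 1.15 higher and bll7008 was 2.75 ± 0.56 higher. All 7 and all 5 members were higher with taurine on both direct arrays. Adjusted over the list alone, 7 of 7 and 4 of 5 members passed, against 0 of each over all genes. The study itself named these clusters, so their list counts and camera results are not independent evidence, here or in any later comparison. By camera the clusters lay above other genes (adjusted p = 3.06e-11 and 1.86e-06), but with an estimated correlation adjusted p = 0.747 for each. Outside them, atoB (bll0226) differed by 1.44 ± 0.21 and blr1508 by -2.84 ± 0.27, the latter at -3.85 and -2.72 on the direct arrays. Over all genes 0 passed (lowest adjusted p = 0.519) and 274 had an unadjusted p under 0.05 in limma, with 413 due by chance. The random block called 5 genes and the replicate block 6, and the random block 191 with the sign of the sulfate and HEPES pair turned. Leaving out an array or a pair moved the random-block count between 1 and 427, the highest without the sulfate and HEPES pair.

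**Figure D1:**
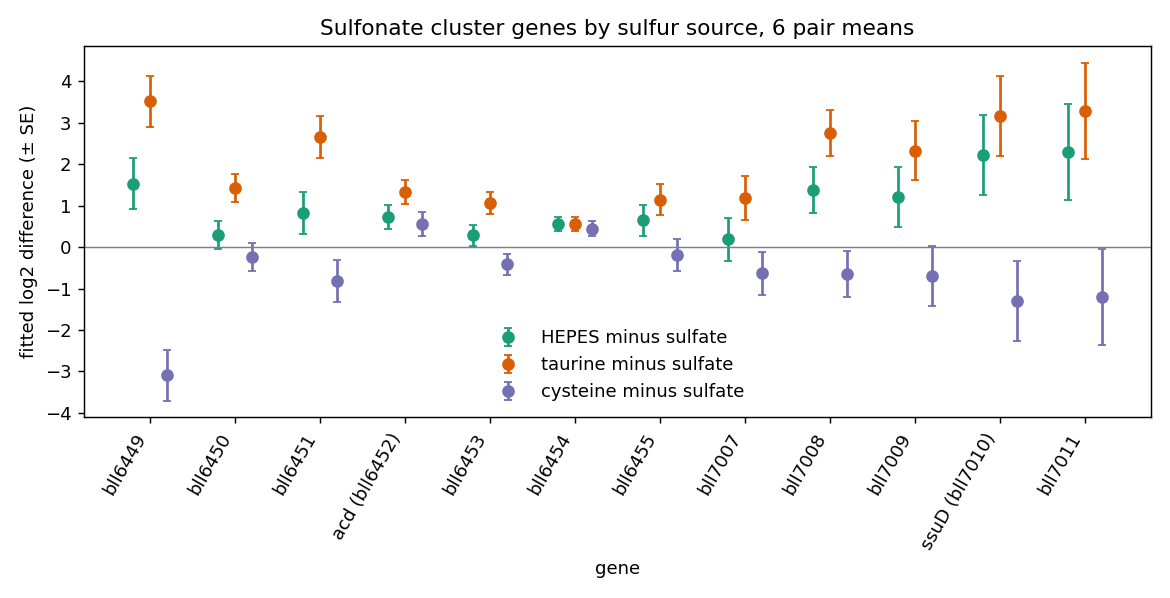
Fitted log2 difference from sulfate (vertical axis; points, bars are ± SE over 6 pair means) of the 12 sulfonate cluster genes (horizontal axis) with HEPES, taurine and cysteine. Taurine values run from 0.55 for bll6454 to 3.51 for bll6449, and the value of bll6449 with cysteine is -3.09.

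With HEPES, the members of the same clusters all had fitted values above sulfate, with medians of 0.64 and 1.37. ssuD (bll7010) was 2.22 ± 0.97 higher, bll7011 was 2.30 ± 1.15 higher and bll6449 was 1.52 ± 0.62 higher, while bll7007 differed by 0.19 ± 0.52 in the fit and by -0.44 and -0.95 on its direct arrays. On both direct arrays 5 of 7 and 4 of 5 members were higher with HEPES, and 0 and 1 lower. The clusters passed camera (adjusted p = 0.00339 and 0.0238), with adjusted p = 0.770 and 0.924 with an estimated correlation; without its most different member the smaller cluster had adjusted p = 0.0685. Adjusted over the list alone 0 members of either passed in limma. Among 46 chaperone and protease genes, 26 were lower with HEPES on both direct arrays and 7 higher, with a median of -0.48. Of the 46, 20 had been added to the list after values were seen. The small heat shock gene hspB (blr5233) differed by -1.51 ± 0.30 and the chaperonin gene groES (blr5625) by -1.44 ± 0.24. That list passed camera (adjusted p = 3.18e-09), and had adjusted p = 0.747 with an estimated correlation; adjusted over the list alone 9 members passed, against 0 over all genes. The 35 nitrogen fixation genes had a fitted median of 0.45 with HEPES over sulfate, 31 of them above 0, while 13 were lower and 7 higher on both direct arrays. They passed camera (adjusted p = 0.00208), with adjusted p = 0.924 with an estimated correlation, and 0 members passed adjusted over the list alone. By the 12-array rule, fixK (bll2757) of that list differed by -3.22 ± 0.70. Also by that rule, bll4247 differed by -2.45 ± 0.50, blr1508 by -2.41 ± 0.27, bll0507 by 1.96 ± 0.37 and atoB (bll0226) by 1.45 ± 0.21.

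The 53 ribosomal protein genes had a median of 0.81 with HEPES over sulfate, and 47 were higher on both direct arrays. All 53 were listed by symbol after values had been seen. They passed camera (adjusted p = 3.52e-05), with adjusted p = 0.924 with an estimated correlation, and 0 members passed adjusted over the list alone. Their median was 2.18 on the sulfate and HEPES arrays themselves and -0.55 when rebuilt from the other 5 pairs, so their direction rests on that pair. With taurine and with cysteine their fitted medians over sulfate were 0.18 and 0.36, while 47 and 49 of them were lower on both direct arrays. For HEPES over taurine the fitted median was 0.48 (camera adjusted p = 2.34e-05, adjusted p = 0.924 with an estimated correlation), while 42 were lower on both direct arrays. Over all genes 0 passed (lowest adjusted p = 0.738) and 495 had an unadjusted p under 0.05 in limma; 7 passed with the random block and 6 with the replicate block. Values on the direct arrays take the labels of the sulfate and HEPES pair as given; with its sign turned the random block called 230. Leaving out an array or a pair moved the random-block count between 1 and 275, the highest without the sulfate and HEPES pair.

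HEPES and taurine were given at the same 2 mM; both carry an ethanesulfonate, on a piperazine ring in HEPES and on an amino group in taurine. The cluster genes were lower with HEPES than with taurine on both direct arrays in 6 of 7 and 5 of 5 members. bll6449 differed by -1.99 (95% interval -3.52 to -0.46), bll6451 by -1.85 (-3.11 to -0.59) and bll6450 by -1.14 (-1.98 to -0.29). For ssuD (bll7010) the difference was -0.94, with an interval from -3.35 to 1.47, and for bll7011 it was -0.99, from -3.86 to 1.88; these intervals allow differences either way, and without the HEPES and taurine pair the values were 0.74 and 0.80. bll6454 differed by 0.01, from -0.43 to 0.44. The clusters passed camera (adjusted p = 5.47e-05 and 0.0168), with adjusted p = 0.747 and 0.924 with an estimated correlation; without its most different member the smaller cluster had adjusted p = 0.0794. Adjusted over the list alone, 4 of 7 and 0 of 5 members passed. Over all genes 0 passed (lowest adjusted p = 0.923), 338 had an unadjusted p under 0.05 in limma, and the random and replicate blocks each called 0. The random block called 17 without HEPES and cysteine array 1 and 99 without that pair. The absence of calls does not show that both compounds act alike.

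With cysteine, 2 genes of sulfate assimilation were lower than with sulfate. cysD (bll1476), for a subunit of sulfate adenylyltransferase, differed by -2.97 ± 0.85, and cysH (blr1481), for a reductase of activated sulfate, by -1.78 ± 0.50. Both stood at -2.40 or lower on each direct array. The other 4 members of that list, all with the symbol cysD, lay between -0.18 and 0.02. Adjusted over the list alone 2 of 6 members passed, against 0 over all genes. The list as a whole did not pass camera (adjusted p = 0.0905). In bll7007 to bll7011 all 5 members were lower with cysteine on both direct arrays, with a median of -0.70; ssuD (bll7010) differed by -1.30 ± 0.97 and bll7011 by -1.20 ± 1.15. In bll6449 to bll6455 2 members were lower and 2 higher, with a median of -0.23; bll6449 differed by -3.09 ± 0.62, acd (bll6452) by 0.56 ± 0.29 and bll6454 by 0.44 ± 0.18. The clusters did not pass camera (adjusted p = 0.369 and 0.0833), and adjusted over the list alone 1 of 7 and 0 of 5 members passed in limma.

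**Figure D2:**
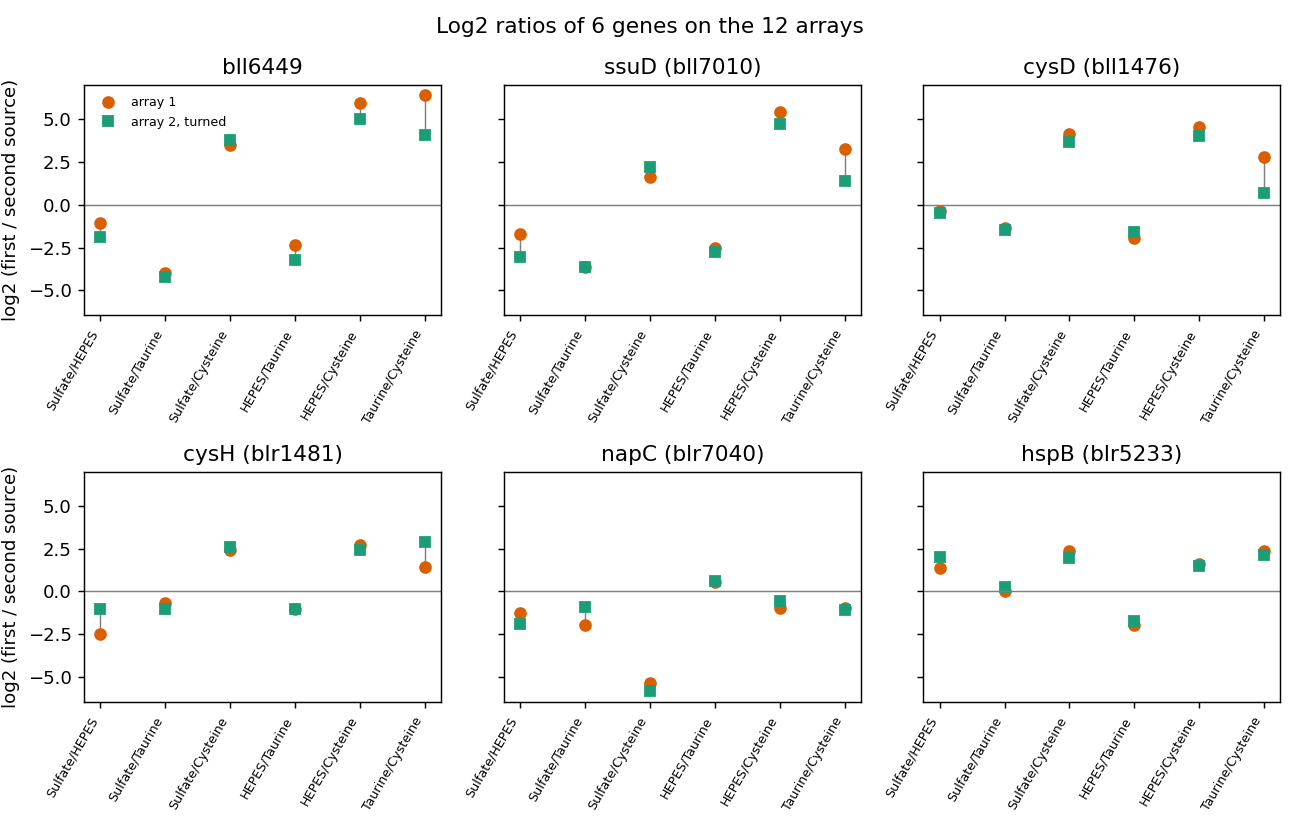
Log2 ratio of the source named first over that named second (vertical axis) of 6 genes on each of the 12 arrays (horizontal axis: pair of sources; circles array 1, squares array 2 after turning). cysD (bll1476) is 4.11 and 3.64 higher with sulfate than cysteine, and napC (blr7040) is 5.32 and 5.83 higher with cysteine on the same arrays.

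The 12 genes with the largest positive values chosen by the 12-array rule with cysteine included genes of nitrate reduction, of a high-affinity oxidase and of haem synthesis. The periplasmic nitrate reductase genes napC (blr7040), napB (blr7039), napD (blr7037) and napE (bsr7036) were higher by 3.99 ± 0.69, 3.84 ± 0.67, 3.51 ± 0.67 and 3.60 ± 0.96. Genes of the high-affinity oxidase and its assembly, fixQ (bsr2765), fixP (blr2766) and fixG (blr5778), were higher by 4.03 ± 1.22, 3.98 ± 1.23 and 3.54 ± 0.67. The haem synthesis genes hemA (bll1200) and hemN (bll7086) were higher by 3.56 ± 0.96 and 3.68 ± 1.26. Of 35 nitrogen fixation genes, 27 were higher with cysteine on both direct arrays and 4 lower; fixK (bll2757) differed by -3.98 ± 0.70. The list passed camera (adjusted p = 1.55e-05), with adjusted p = 0.770 with an estimated correlation, and 2 members passed adjusted over the list alone. A set of 63 low-oxygen genes was grouped after the data were examined. Their median less that of all genes was 1.97 on the direct arrays. Rebuilt through the other sources it was 0.37, with -0.0018 through HEPES and 0.75 through taurine. The bootstrap SE of 0.37 was 0.17, a spread among genes and not between arrays.

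Of 46 chaperone and protease genes, 36 were lower with cysteine on both direct arrays and 3 higher. hspB (blr5233) differed by -2.48 ± 0.30. The list passed camera (adjusted p = 5.03e-11), with adjusted p = 0.747 with an estimated correlation; 11 members passed adjusted over the list alone. The list also passed camera for taurine minus sulfate (median -0.12, 23 lower and 8 higher on both direct arrays, adjusted p = 0.000624), HEPES minus taurine (-0.29, adjusted p = 0.000994) and taurine minus cysteine (0.22, adjusted p = 0.000436). With an estimated correlation these had adjusted p = 0.762, 0.770 and 0.762, and 0, 0 and 9 members passed adjusted over the list alone. leuA (bll6435) and argD (blr4582), of leucine and arginine synthesis, differed by -2.30 ± 0.56 and -2.28 ± 0.45. Among genes without a symbol, blr3188 differed by -3.81 ± 0.79, blr2887 by -3.14 ± 0.63 and bsl4569 by -3.13 ± 0.47. blr1508, lower than with sulfate with taurine and HEPES too, differed by -2.21 ± 0.27 with cysteine. bll4247, lower with HEPES too, differed by -2.24 ± 0.50. Over all genes 0 passed (lowest adjusted p = 0.369) and 790 had an unadjusted p under 0.05 in limma; 201 passed with the random block (127 higher, 74 lower) and 255 with the replicate block. The random block called 351 with the sign of the sulfate and HEPES pair turned, 26 without the sulfate and cysteine pair and 706 without the sulfate and HEPES pair.

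Against cysteine, the sulfonate clusters were higher with either sulfonate. bll6449 was 6.60 ± 0.62 higher with taurine and 4.61 ± 0.62 higher with HEPES, and ssuD (bll7010) was 4.46 ± 0.97 higher with taurine. The clusters passed camera with taurine (adjusted p = 2.73e-08 and 1.02e-06) and with HEPES (adjusted p = 1.85e-06 and 6.43e-07), with adjusted p = 0.747 with an estimated correlation in each. Adjusted over the list alone 6 of 7 and 5 of 5 members passed with taurine, and 1 of 7 and 4 of 5 with HEPES. blr3188 was 4.54 ± 0.79 higher with taurine and 5.00 ± 0.79 higher with HEPES. cysD (bll1476) and cysH (blr1481) were 3.70 ± 0.85 and 2.81 ± 0.50 higher with taurine. The 2 direct arrays of taurine and cysteine, which correlated at -0.17 after turning, gave mostly smaller values. On them cysD stood at 2.79 and 0.69, cysH at 1.45 and 2.85, and ssuD at 3.24 and 1.39. blr3188 stood at 3.94 and 2.45, and bll6449 at 6.37 and 4.04. The sulfate list passed camera against cysteine for HEPES (adjusted p = 0.000994) and taurine (adjusted p = 0.00361), with adjusted p = 0.747 with an estimated correlation in each; 2 members passed adjusted over the list alone in each. The nitrogen fixation list passed camera downward against cysteine for HEPES (median -0.17, adjusted p = 0.0217) and taurine (median -0.55, adjusted p = 0.00484), with adjusted p = 0.924 with an estimated correlation in each. On both direct arrays 13 members were lower and 5 higher with HEPES, and 8 lower and 6 higher with taurine; 0 passed adjusted over the list alone. The 53 ribosomal protein genes had a median of 0.43 with HEPES over cysteine (adjusted p = 0.000158 by camera, adjusted p = 0.924 with an estimated correlation), 29 higher and 5 lower on both direct arrays. Lower than with cysteine were bll0148, by -2.96 ± 0.48 with taurine and -3.07 ± 0.48 with HEPES, and bll1007, by -2.58 ± 0.43 and -2.77 ± 0.43. On the direct arrays with taurine, bll0148 stood at -3.87 and -3.75, and bll1007 at -1.64 and -1.76. The terminal oxidase gene cyoC (blr0151) differed by -2.47 ± 0.41 with HEPES. In limma 0 genes passed for either (lowest adjusted p = 0.216 with taurine and 0.420 with HEPES); 734 (taurine) and 184 (HEPES) had an unadjusted p under 0.05. The random block called 122 and 17, and the replicate block 201 and 19; with taurine and cysteine array 2 unturned the random block called 0 for both. Leaving out an array or a pair moved the random-block counts between 31 (without sulfate and taurine) and 607 (without sulfate and HEPES) for taurine, and between 6 (without HEPES and cysteine array 1) and 69 (without HEPES and taurine) for HEPES.

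With both sulfonates set against sulfate and cysteine, the clusters had medians of 0.98 and 2.39 and passed camera (adjusted p = 5.21e-12 and 1.01e-08), with adjusted p = 0.747 with an estimated correlation. Adjusted over the list alone 7 of 7 and 5 of 5 members passed. Since the study named the clusters, neither result is independent evidence. Over all genes 0 passed, 264 had an unadjusted p under 0.05 in limma, and the random and replicate blocks called 21 and 25, the random block between 5 (without HEPES and cysteine) and 121 (without sulfate and HEPES). For any difference among the 4 sources 0 genes passed the moderated F test and 447 had an unadjusted p under 0.05; the blocks called 124 and 194, the random block between 30 (without sulfate and taurine) and 785 (without sulfate and HEPES). Calls from the 12 arrays also rest on the turning of taurine and cysteine array 2: left unturned, the random block called 1 gene for any difference and 0 for the sulfonates. Also passing camera were genes of reduced sulfur oxidation (median -0.24, taurine minus cysteine, adjusted p = 0.00531), efflux and metal resistance (0.69, HEPES minus sulfate, adjusted p = 0.00595) and flagella and chemotaxis (0.23, HEPES minus sulfate, adjusted p = 0.0217). With an estimated correlation these had adjusted p = 0.747, 0.770 and 0.911, and 0 members of each passed adjusted over the list alone in limma. Reduced sulfur oxidation also passed for cysteine minus sulfate (0.22, adjusted p = 0.0354) and HEPES minus cysteine (-0.15, adjusted p = 0.0485), with adjusted p = 0.747 and 0.756 with an estimated correlation. Without its most different member it had adjusted p = 0.121 in each, and 1 and 0 members passed adjusted over the list alone in limma. Efflux and metal resistance passed for HEPES minus cysteine (0.21, adjusted p = 0.0217) and the sulfonates (0.13, adjusted p = 0.00525), with adjusted p = 0.911 and 0.770 with an estimated correlation; without its most different member the former had adjusted p = 0.147. For the sulfonates the sulfate list (0.33, adjusted p = 0.00116) and ribosomal proteins (0.29, adjusted p = 0.00668) passed camera too. With an estimated correlation they had adjusted p = 0.747 and 0.932. On both direct arrays 47 of 53 ribosomal protein genes were higher with HEPES than with sulfate, but 47 were lower with taurine. Against cysteine 29 were higher and 5 lower with HEPES, and 2 higher and 25 lower with taurine. Of the lists with topics fixed before the data were examined, 8 passed in no comparison, and their lowest adjusted p was 0.0628 by camera. Cysteine and methionine metabolism and redox and thiol stress were among them, the latter with all 15 members written out after values had been seen.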

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

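Settings added after the data were examined were loess on each array's own intensities, a spread trend, brighter genes only, leaving out a pair, the unturned array, and every change to the random-block fit. The fit of 6 pair means called 0 genes in all comparisons under the values as deposited, median centring, robust eBayes, single probes and the added settings other than left-out pairs. Scaling the arrays called 1 gene for cysteine and sulfate. Leaving out arrays or pairs gave 0 to 1 for taurine and cysteine and 0 to 1 for the sulfonates, the 1 arising without taurine and cysteine array 2 or that pair. For any difference, HEPES and sulfate, taurine and sulfate, cysteine and sulfate, HEPES and cysteine, taurine and cysteine, and the sulfonates, in that order, the pair as random block called 124, 7, 5, 201, 17, 122 and 21. Independent arrays called 159, 11, 6, 227, 18, 148 and 29, and the replicate block 194, 6, 6, 255, 19, 201 and 25. The replicate block shared 199 of its cysteine and sulfate calls with the random block and called 0 for HEPES and taurine. Direct arrays called 1240 for HEPES and sulfate, 150 for taurine and sulfate, 462 for cysteine and sulfate, 217 for HEPES and taurine, 62 for HEPES and cysteine and 182 for taurine and cysteine. These fits use the 2 arrays of a pair as replicates, which gives them more residual degrees of freedom than 6 pair means.

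In the random-block fit, the values as deposited gave 8 for taurine and sulfate, 1 for HEPES and taurine and 9 for HEPES and cysteine, and median centring 8 for taurine and sulfate. With taurine and cysteine array 2 unturned it called 1 each for any difference, HEPES, taurine and cysteine against sulfate, and 0 for the others. Leaving out arrays or pairs gave 30 to 785 for any difference, 1 to 275 for HEPES and sulfate, 1 to 427 for taurine and sulfate, 26 to 706 for cysteine and sulfate, 0 to 99 for HEPES and taurine, 6 to 69 for HEPES and cysteine, 31 to 607 for taurine and cysteine, and 5 to 121 for the sulfonates; the cause was not tested. Of 119 list tests 35 passed with the preset correlation, 32 without each list's most different member (5 calls ended and 2 arose), 0 with an estimated correlation and 0 by fry. Of 154 gene differences that the rule or the text names, 38 turned sign in at least 1 setting, and 13 on the direct arrays. Of the 38, 1 had a fitted difference of at least 1 log2 in size in the fit of 6 pair means. Of the 101 followed one by one, 9 turned. For HEPES minus taurine, bll7009, ssuD (bll7010) and bll7011 were 0.23, 0.74 and 0.80 without their direct pair. With arrays or pairs left out they were lowest, at -1.87, -2.01 and -2.29, without the taurine and cysteine pair. On direct arrays only they were -2.47, -2.62 and -2.78. With arrays or pairs left out, bll6454 ranged from -0.043 to 0.061. It was 0.21 as deposited, 0.078 with own-intensity loess, -0.087 on scaled arrays and -0.0011 with array 2 unturned. For HEPES minus sulfate, bll7007 was -0.70 on direct arrays and ranged from -0.34 to 1.07 with arrays or pairs left out. For cysteine minus sulfate, leaving out gave -0.32 to 0.033 for bll0245, -0.38 to 0.41 for bll1235, -0.37 to 0.16 for bll6281 and -0.26 to 0.30 for blr4967. As deposited blr4967 was -0.30 and on single probes -0.27. Median centring, scaling, direct arrays, own-intensity loess and the unturned array gave 0.084, 0.074, 0.35, 0.057 and 0.22 for bll6281 and -0.042, -0.073, -0.19, -0.073 and -0.33 for blr4967, and the unturned array 0.18 for bll1235. Recovered intensities are lower bounds, and no signal over background was used here.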

Other observations

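The tests of low-oxygen genes and of the sulfate and HEPES pair were chosen after the values had been seen, as were 5 added gene lists; the tests of neighbouring genes, of the taurine and cysteine arrays and of sign assignments were set before their results were seen, those with the replicate block after the random-block ones were known, and those of HEPES and of taurine against sulfate, HEPES against cysteine and the sulfonates after their counts were seen. Of 19 denitrification genes, all 19 were higher with cysteine than with sulfate on both direct arrays, with a fitted median of 1.88, and 12 passed adjusted over the list alone. Of 9 cytochrome c maturation genes, 8 were higher and 1 lower, with a median of 1.66. Both lists passed camera (limma, adjusted p = 2.87e-12 and 1.40e-07), and had adjusted p = 0.569 with an estimated correlation. Both had been chosen for high values with cysteine over sulfate, so these tests are not independent evidence. With taurine the denitrification median over sulfate was 1.23, with 14 of 19 higher and 1 lower on both direct arrays (adjusted p = 4.22e-08), and the cytochrome c maturation median was 1.16, with 9 of 9 higher (adjusted p = 1.52e-06); each had adjusted p = 0.569 with an estimated correlation. With HEPES the fitted denitrification median over sulfate was 0.94 (adjusted p = 1.71e-06), with 18 of 19 above 0 but 6 higher and 5 lower on both direct arrays. The cytochrome c maturation median was 1.20 (adjusted p = 4.94e-05), with 2 higher and 2 lower. These had adjusted p = 0.613 and 0.569 with an estimated correlation. Against cysteine the denitrification medians were -0.99 with HEPES (adjusted p = 4.22e-08) and -0.68 with taurine (adjusted p = 4.94e-05), with adjusted p = 0.569 and 0.671 with an estimated correlation. On both direct arrays 4 were higher and 8 lower with HEPES, and 0 higher and 6 lower with taurine. The cytochrome c maturation medians against cysteine were -0.64 with HEPES (adjusted p = 0.000107) and -0.56 with taurine (adjusted p = 0.00595), with adjusted p = 0.569 and 0.671 with an estimated correlation. On both direct arrays 0 were higher and 5 lower with HEPES, and 1 higher and 5 lower with taurine. The nitrogen fixation list, fixed before the data were examined, had a median of 0.31 with taurine over sulfate, with 17 of 35 higher and 9 lower on both direct arrays, and did not pass camera (adjusted p = 0.0648). Among the other added lists, cell division and wall genes passed camera for HEPES minus taurine (median 0.37, adjusted p = 1.71e-06), hydrogenase and CO2 fixation genes for taurine minus sulfate (0.23, adjusted p = 0.000167) and amino acid synthesis genes for HEPES minus cysteine (0.12, adjusted p = 0.00486). With an estimated correlation they had adjusted p = 0.569, 0.613 and 0.872. Cell division and wall genes also passed for HEPES minus sulfate (0.32, adjusted p = 0.000219), cysteine minus sulfate (0.40, adjusted p = 0.000297) and taurine minus cysteine (-0.44, adjusted p = 2.43e-05), each with adjusted p = 0.569 with an estimated correlation. For cysteine minus sulfate, hydrogenase and CO2 fixation genes (0.17, adjusted p = 0.0470) and amino acid synthesis genes (-0.01, adjusted p = 0.0473) passed, with adjusted p = 0.900 and 0.901 with an estimated correlation, and adjusted p = 0.0618 and 0.0856 without their most different member.

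Genes of the nitrogen fixation, denitrification and cytochrome c maturation lists (63 in all, the last 2 lists chosen for such values) had high values with cysteine over sulfate. On both direct arrays 54 of them were higher. fixK (bll2757) of this group went the other way, at -3.98 ± 0.70 with cysteine over sulfate. A dye effect of each gene cancels in the mean of that pair's arrays, which ran opposite as deposited (r = -0.84), so it was not tested further. A difference of that pair of cultures alone stays open: less that of all genes, the median was 1.97 on the direct arrays and 0.37 (bootstrap SE 0.17) when rebuilt through the other sources, with -0.0018 through HEPES and 0.75 through taurine. Gene by gene, direct values exceeded rebuilt ones by a median of 1.33 (bootstrap SE 0.39). Both bootstraps resampled genes as if unrelated, so these SEs measure spread among genes, not between arrays or cultures. A hypothesis is that oxygen may have differed between these cultures as well as the sulfur source; oxygen was not a variable of the design, and this was not tested.

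The values of 2 pairs correlated negatively across genes with those rebuilt from the other 5 pairs: sulfate and HEPES at -0.24 and HEPES and taurine at -0.10, against 0.19 to 0.43 for the other 4. Sums around each triangle of sources, 0 where pairs agree, were a check chosen before the data were examined. For sulfate, HEPES and taurine their standard deviation over genes was 1.18, against 1.08 for unrelated pairs. With cysteine in place of taurine it was 1.28 against 1.27. It was 0.72 against 1.12 for sulfate, taurine and cysteine, and 0.79 against 0.84 for HEPES, taurine and cysteine. Triangles with the sulfate and HEPES pair thus closed no better than unrelated pairs would. That pair was followed up. Whether the sources of sulfate and HEPES were exchanged cannot be told apart from a difference between cultures: the 12 sulfonate cluster genes had a median of 0.61 higher with HEPES on its arrays (bootstrap SE 0.33), under the bound set of 2 SE, with 9 of 12 higher on both arrays, and 1.06 from the other pairs. The bootstrap resampled the 12 genes as if unrelated. Its SE and the bound therefore measure spread among these genes, not between arrays or cultures. Chaperone genes had medians of -0.51 and -0.39, of the same sign, and ribosomal protein genes 2.18 and -0.55, of opposite sign.

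Genes with large differences lay next to each other. Among the 100 genes with the largest cysteine and sulfate statistic there were 12 adjacent pairs on the same strand, against at most 6 in 10000 random draws, so chance position is argued against. Across the 6 pair means, neighbours by locus number on the same strand correlated by 0.20 (SE 0.012) more than neighbours on opposite strands. Mean r was 0.32 and 0.12, and -0.00082 for random genes. Positions of probes on the array were not used, so an error shared by nearby spots was not tested. The difference by strand argues against an error shared alike by neighbours in locus order as the whole cause. A hypothesis consistent with this is shared transcripts of neighbouring genes; the values do not say which source drives them.

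Signs were also assigned to the 6 pairs in all 32 ways in the random-block fit. For any difference, 10 of 32 gave at least the real 124 genes (highest other 459). For HEPES and sulfate 16 gave at least 7 (highest other 540), for taurine and sulfate 9 at least 5 (222), for cysteine and sulfate 9 at least 201 (365), for HEPES and cysteine 6 at least 17 (289) and for the sulfonates 4 at least 21 (214), so chance is not excluded for any of these. For taurine and cysteine 1 of 32, the real one and the smallest share possible, gave 122, the highest other 110. With the replicate block, which keeps the dye term, 8 of 32 gave at least 194 for any difference (highest other 790), 17 at least 6 for HEPES and sulfate (816), 10 at least 6 for taurine and sulfate (431), 9 at least 255 for cysteine and sulfate (491), 6 at least 19 for HEPES and cysteine (503) and 5 at least 25 for the sulfonates (551). It gave 201 for taurine and cysteine in 1 of 32, the real one (highest other 175). With either block, every other assignment that reached the real count for cysteine and sulfate turned sulfate and HEPES against the other pairs with sulfate. Whether that turn is the true one stays open, so those assignments are not plain chance draws. With 32 assignments the test could hardly have excluded chance. The count for taurine and cysteine is the favourable one of 7 comparisons with calls, and the random block called 0 with array 2 unturned, so chance is not taken as excluded there either. HEPES and taurine had 0 calls in limma by both blocks and in the pair means, with 338 at an unadjusted p under 0.05, and were not tested in this way. Assignments that call several times the real count point to a structure of the samples. Turning the sulfate and HEPES pair alone gave 308 genes for any difference, 230 for HEPES and sulfate, 191 for taurine and sulfate and 351 for cysteine and sulfate, and whether its sources were exchanged or its cultures differed stays open. The 2 taurine and cysteine arrays correlated at -0.17 after turning and at 0.13 once the dye effect of each gene, taken from the other 5 pairs, was removed; the other pairs then correlated at 0.45 to 0.79, so the disagreement was reduced and not resolved.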
